A study of Mus musculus with 16 samples.

How the data were processed

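Bulk RNA sequencing of the mouse dorsal hippocampus was available as 16 libraries, 4 in each combination of virus (GFP control or Dnmt3a2) and day (1 or 5 days after contextual fear conditioning). Per the labels, 500 ng of total RNA was used per library, purified with a spin column kit, and sequencing was on a BGISEQ-500 instrument. The authors' notes name Trim Galore 0.6.4, kallisto 0.4.6, edgeR 3.17 and genome build GRCm38.p6. The order of the steps, the annotation release, the strand of the counting and how transcripts were summed to genes are not given in the sources used here.

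Each library had 2 files. The deposited expected counts are estimated read counts for 55385 Ensembl gene identifiers, not normalised, with 26.2% of values not whole. The deposited log2 values are CPM on the log2 scale for 16907 genes. They were checked against edgeR's log2 CPM of the deposited counts after its filterByExpr filter by group and TMM scaling, and differed by at most 5.329e-15. Totals were 28.6 to 30.0 M per library, so 1 CPM stands for 28.6 to 30.0 estimated counts. Whether counting error or spread between libraries limits a given comparison was not tested. Library pairs were checked for duplicates: the chi-square per gene ran from 4.43 to 43.99 over 120 pairs, where 1 would be expected of a repeated library.

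Counts were rounded, filtered with filterByExpr by group and scaled with TMM in edgeR 4.0.16 under R 4.3.3. This left 16899 genes to test, and 15 genes of the authors' 16907 were not among them. Of the identifiers, 55144 were named with GENCODE M21, 16887 of them among the tested genes. All 16 libraries entered 1 robust quasi-likelihood fit with a term per group. Contrasts were Dnmt3a2 against control at 1 day, at 5 days and averaged over both, 5 days against 1 day in each virus group, and the difference of the Dnmt3a2 effects between days. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Dnmt3a was also tested with an exact two-sided permutation test of CPM over the 70 regroupings at each day, whose smallest p is 0.0286.

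A set of 40 gene lists with 1255 symbols, 1186 of them tested, covered DNA methylation, neuronal activity, synapses, channels, stress, immunity and the cell types the dissection could hold. They were tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 40 lists within each comparison, and again with an estimated correlation. Fry tested whether a list's genes moved on balance in 1 direction, and fry calls below are of this kind unless stated. A second form of fry tested whether members changed in either direction. Calls among list members were counted over all genes tested and adjusted over the list alone. The groups, tests, lists, most of the other settings and the rule for naming genes were chosen before the data were examined. The rule took called genes with a mean of at least 1 CPM in the higher group, no overlap between the libraries of the groups and an established symbol: the 8 largest rises and falls and the 4 smallest adjusted p each way, or 5 and 2 for the comparisons between days. Where none passed, the 5 genes with the smallest p were given as values. Up to 2 rising and 2 falling members of each list, and Dnmt3a throughout, were added. Genes named after their values were seen were Ttr, Enpp2, the Y-linked genes and their X-linked counterparts, and Xist.

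The alternatives tried were DESeq2's size factors and its Wald test (version 1.42.0), upper-quartile factors, no low-count filter, a mean CPM of at least 1, no robust estimation, limma-voom, limma-trend on the authors' log2 scale with pseudocounts of 1 and 0.1, 1 surrogate variable (sva 3.50.0), the replicate number as a block, only the groups compared, an adjusted p of 0.10, a fold of at least 1.5, and each library left out. Alternatives added after seeing the data left out the 2 libraries rich in choroid plexus transcripts or the 3 rich in interferon response transcripts, used the choroid plexus score as a covariate, used offsets for GC content and transcript length, and took Dnmt3a out of the methylation list. The main model had no block, a choice made before the data were examined, since the labels pair no samples beyond a replicate number. Replicate numbers were also checked for pairing. Among libraries of other groups, 6 of 16 correlated best with one of their own number, which does not exclude pairing. The highest correlations among the 24 pairs of equal number, 0.380, 0.273 and 0.223, joined replicate 1 of Control_1d, Dnmt3a2_1d and Dnmt3a2_5d. These are the 3 interferon-rich libraries and include the 2 choroid-rich ones. Control_5d replicate 1 did not join them (-0.086 to -0.009). Whether they share a batch was not tested.

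The fit was tested on simulated data in which each gene was drawn independently and 200 genes with a mean of at least 1 CPM were changed. At 1 day it recovered 18.0% of genes changed 1.2-fold, 64.0% at 1.5-fold, 90.0% at 2-fold and 98.0% at 3-fold, and at 5 days 20.0%, 58.0%, 90.0% and 98.0%. The average over both days recovered 54.0%, 80.0%, 94.0% and 98.0%. Among the unchanged genes it called 5 at 1 day, 12 at 5 days and 10 in the average. Simulated comparisons without changes called 0 genes in edgeR, with 762 to 789 at an unadjusted p under 0.05. In the data, edgeR gave 598 between days in controls, 1822 in Dnmt3a2 mice and 360 for the interaction at that threshold. The simulation left out variation shared between genes, so its rates may not hold for these libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Transcript isoforms were not analysed here. Results for some genes are not reported here.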

Results

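RNA from the dorsal hippocampus of mice was sequenced as 16 libraries. A recombinant adeno-associated virus had delivered either GFP, the control, or exogenous Dnmt3a2, the short isoform of the de novo DNA methyltransferase Dnmt3a. Contextual fear conditioning, in which an animal learns to associate a place with a foot shock, followed 3 weeks after injection, and tissue was taken 1 day or 5 days later. Each of the 4 combinations of virus and day had 4 libraries, referred to as Control and Dnmt3a2 at 1 day (1d) and at 5 days (5d). Total estimated counts (in M) were 28.7 to 29.9 M in Control_1d, 28.8 to 29.7 M in Dnmt3a2_1d, 28.6 to 29.8 M in Control_5d and 29.8 to 30.0 M in Dnmt3a2_5d. Levels are given in CPM, counts scaled to a common library total, as mean ± SD over 4 libraries, and positions are on mouse genome build GRCm38.p6. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these samples.

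The first question was how far the virus raised its target. Dnmt3a (ENSMUSG00000020661, a protein-coding gene on chromosome 12 at 3806007 to 3914443) rose from 34.8 ± 0.797 CPM in controls to 964 ± 238 CPM at 1 day, a ratio of 27.7. At 5 days it rose from 35.1 ± 2.15 to 1161 ± 110 CPM, a ratio of 33.0. The lowest Dnmt3a2 library, Dnmt3a2_1d replicate 1, held 623.2 CPM and the highest 1249 CPM. Counts per gene do not separate the delivered sequence from the endogenous gene. The log2 fold changes were 4.79 (SE 0.17, edgeR adjusted p = 2.19e-09) and 5.05 (SE 0.17, edgeR adjusted p = 1.27e-09). An exact two-sided permutation test of CPM gave p = 0.0286 at each day, the smallest that 70 regroupings of 8 libraries allow. The increase did not differ detectably between days (difference 0.25, SE 0.21, edgeR adjusted p = 1).

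**Figure D1:**
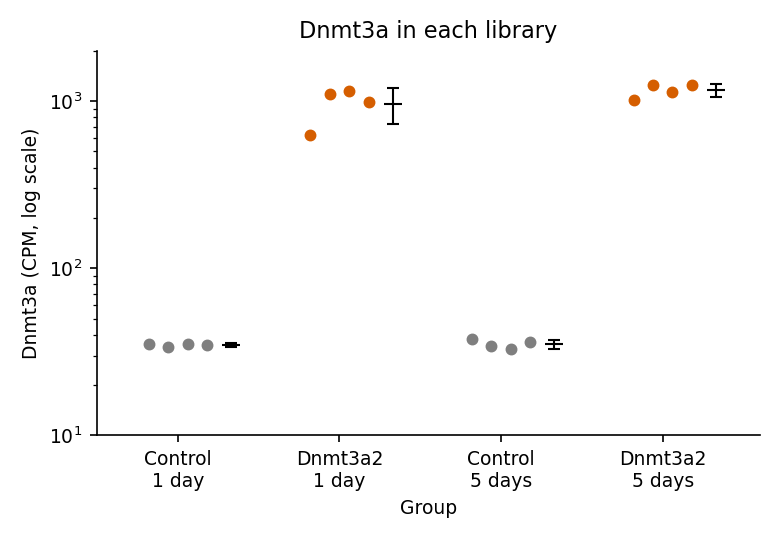
CPM of Dnmt3a on a log axis for each group, with dots for libraries, dashes for means and bars for the SD (n = 4 per group). Every Dnmt3a2 library lies at or above 623.2 CPM, while the control means are 34.8 and 35.1 CPM.

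At 1 day, the comparison asks which hippocampal transcripts differ with Dnmt3a2 soon after conditioning. All 4 groups were conditioned, so no difference here can be tied to memory itself. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), which encodes the enkephalin opioid peptide precursor, rose from 35.9 ± 4.07 to 56.1 ± 4.20 CPM, or 1.56-fold (SE of log2 0.08, edgeR adjusted p = 0.00128). Net1 (ENSMUSG00000021215, chromosome 13, 3882018 to 3918220), a guanine nucleotide exchange factor for RhoA, rose 1.5-fold from 37.6 ± 2.56 CPM (log2 0.59, SE 0.08, edgeR adjusted p = 0.00128). Htr2a (ENSMUSG00000034997, chromosome 14, 74640840 to 74709494), the serotonin 2A receptor, rose 1.66-fold from 10.6 ± 1.04 to 17.6 ± 3.00 CPM (SE of log2 0.13, edgeR adjusted p = 0.0253). The BMP antagonist Grem1 (ENSMUSG00000074934, chromosome 2, 113746164 to 113758646) rose 1.97-fold from 6.61 ± 0.357 to 13 ± 1.03 CPM (SE of log2 0.16, edgeR adjusted p = 0.0113). Calb1 (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064), the calcium-binding protein calbindin, rose 1.31-fold from 96.0 ± 12 to 125 ± 5.22 CPM (SE of log2 0.07, edgeR adjusted p = 0.0241). Falls were largest for Umodl1 (ENSMUSG00000054134, chromosome 17, 30954640 to 31010710), from 3.08 ± 0.135 to 1.22 ± 0.377 CPM, a log2 change of -1.33 (SE 0.18, edgeR adjusted p = 0.00196). The hexokinase-like gene Hkdc1 (ENSMUSG00000020080, chromosome 10, 62383137 to 62422491) changed by -1.29 (SE 0.21, edgeR adjusted p = 0.0118) from 2.12 ± 0.624 to 0.863 ± 0.0726 CPM.

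Smaller falls were found for Ier5l, a relative of an immediate early gene, Hunk, a kinase related to AMPK, and Extl1, an enzyme of heparan sulphate synthesis. Their log2 changes were -0.44, -0.35 and -0.29 (SE 0.08, 0.06 and 0.05), with edgeR adjusted p = 0.0175, 0.033 and 0.0113. Some other genes overlap a neighbour in position, and the strand of the counting is not given in the sources used here. Their change is therefore treated as uncertain, and whether the overlapping transcripts share sequence was not checked. Ecm2 (ENSMUSG00000043631), an extracellular matrix protein, and Ogn, the proteoglycan osteoglycin, lie within Cenpp on the opposite strand, a gene averaging 0.84 CPM. Ecm2 counts rose 1.93-fold from 4.16 ± 0.636 to 8.06 ± 1.11 CPM and Ogn counts 1.71-fold from 5.53 ± 1.44 to 9.44 ± 0.983 CPM (edgeR adjusted p = 0.00281 and 0.0379). Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), skeletal muscle alpha-actin, closely resembles other actin genes and overlaps the predicted gene Gm20388 (16.4 CPM). Its counts fell from 7.89 ± 0.93 to 3.73 ± 0.863 CPM (log2 -1.08, SE 0.15, edgeR adjusted p = 0.00214).

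In edgeR, 15 of 16899 genes passed an adjusted p of 0.05 at 1 day, 9 higher and 6 lower, and 1212 passed at an unadjusted p under 0.05. In all 15 the libraries of the groups did not overlap, which chance gives for 2.86% of genes and which held for 3.43% of all genes. Being called selects genes for such separation, so this is no separate support. The median absolute log2 change of the 15 was 0.73. With offsets for GC content and transcript length, chosen after seeing the data, 18 genes were called, 8 higher and 10 lower. The count fell to 6 without Control_1d replicate 2, to 7 without Dnmt3a2_1d replicate 3 and to 7 when only the groups compared were fitted. It was 34 without a low-count filter, 25 with 1 surrogate variable, 24 with the choroid plexus score as a covariate and 59 by DESeq2. The calls of Penk, Net1, Ecm2, Acta1 and Umodl1 held under each of 32 alternatives. Leaving out Control_1d replicate 2 ended those of Calb1, Extl1, Grem1, Hkdc1, Htr2a, Hunk, Ier5l and Ogn (edgeR adjusted p = 0.0811 to 0.11). Leaving out Dnmt3a2_1d replicate 3 ended the same calls except that of Grem1 (edgeR adjusted p = 0.0709 to 0.11). Single other libraries ended up to 4 of the calls, among them Calb1, Htr2a, Hunk, Ier5l and Ogn, with edgeR adjusted p up to 0.123. They were Control_1d replicates 1, 3 and 4, Dnmt3a2_1d replicates 1 and 2, Control_5d replicates 1 to 4, and Dnmt3a2_5d replicates 2 and 3. Without the 3 interferon-rich libraries, a fit chosen after seeing the data, 6 of the calls ended, those of Calb1, Extl1, Grem1, Htr2a, Hunk and Ogn (edgeR adjusted p = 0.0573 to 0.104). That of Ogn also ended without the 2 choroid-rich libraries (edgeR adjusted p = 0.0783) and with GC offsets.

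**Figure D2:**
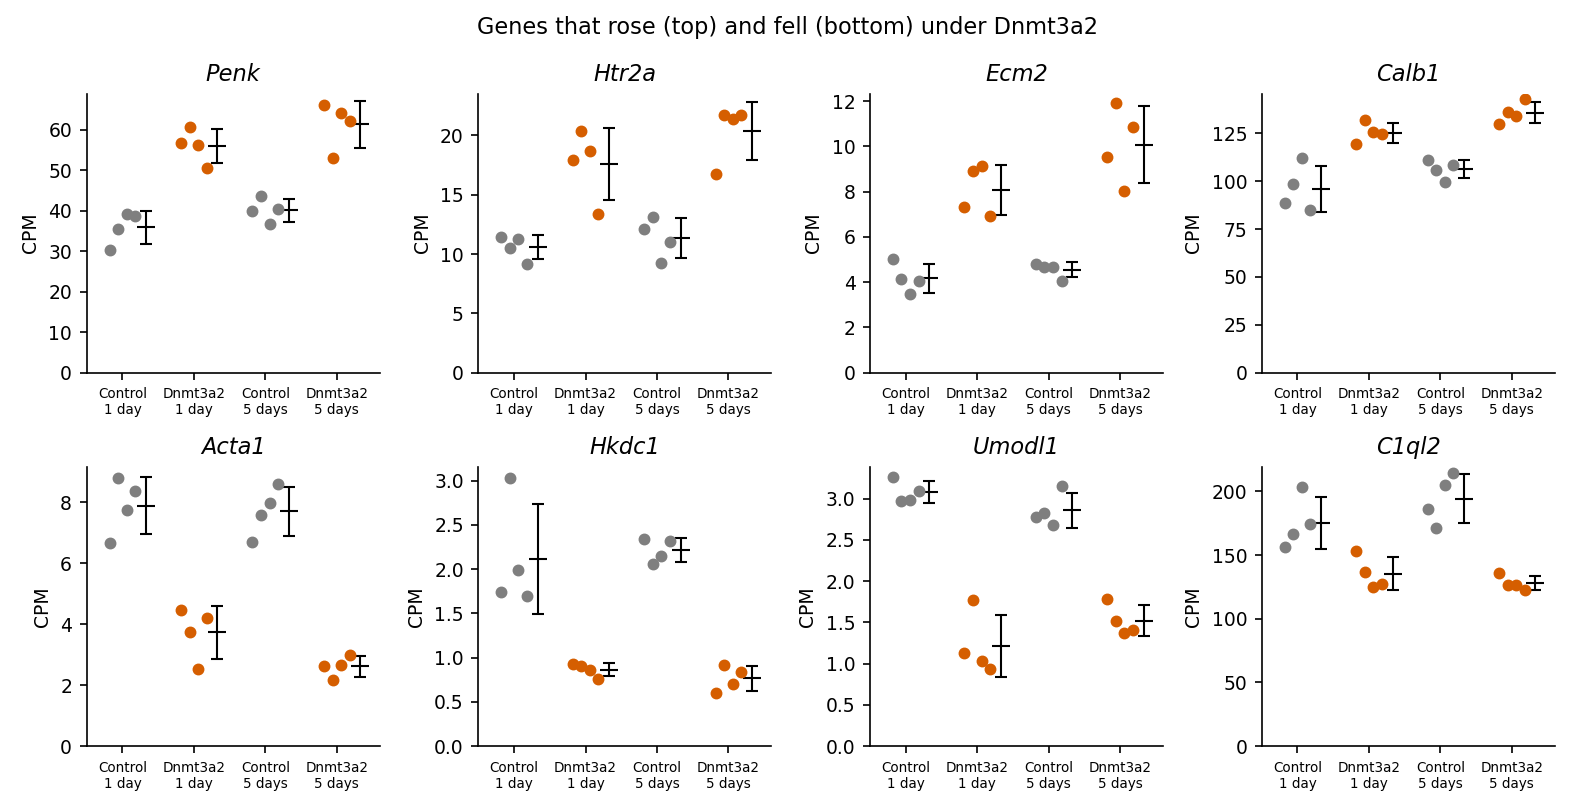
CPM of Penk, Htr2a, Ecm2 and Calb1 in the top panels and of Acta1, Hkdc1, Umodl1 and C1ql2 in the bottom panels, with dots for libraries, dashes for means and bars for the SD (n = 4 per group). Penk lies at means of 56.1 and 61.4 CPM in the Dnmt3a2 groups against 35.9 and 40.2 CPM in controls, and Acta1 at 3.73 and 2.61 CPM against 7.89 and 7.70 CPM.

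Among the gene lists at 1 day, interferon response genes lay higher with Dnmt3a2 in 47 of 53 members, with a median log2 change of 0.331, though none of the members passed alone. Libraries differed widely on this list: Control_1d replicate 1, Dnmt3a2_1d replicate 1 and Dnmt3a2_5d replicate 1 scored 0.58, 0.88 and 1.032 (mean log2 CPM of the list relative to all libraries), and the others -0.541 to 0.17. Heat shock and unfolded protein response genes were above 0 in 30 of 38 (median 0.165), glucocorticoid-responsive genes in 24 of 29 (0.169) and astrocyte markers in 23 of 28 (0.111). Choroid plexus markers were above 0 in 25 of 25 (median 1.059), and 1 library, Dnmt3a2_1d replicate 1, carried most of this. Ttr, the transthyretin made by choroid plexus, was at 773.3 CPM in that library. It was at 1253 CPM in Dnmt3a2_5d replicate 1, which is outside this comparison. In the other Dnmt3a2_1d libraries Ttr did not exceed 86.59 CPM. On the heat shock list, Dnmt3a2_1d replicates 1 and 4 scored 0.408 and 0.222, and replicates 2 and 3 -0.089 and -0.013. On the glucocorticoid list, Dnmt3a2_1d replicates 1 and 4 scored 0.269 and 0.47, replicates 2 and 3 -0.038 and 0.014, and Control_1d replicate 4 scored 0.239.

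Camera with a preset correlation called 10 of 40 lists at 1 day, 8 up and 2 down. None held when the correlation was estimated: every call had adjusted p = 0.894 with an estimated correlation. With the preset correlation, the adjusted p values were 9.35e-06 for interferon response and for heat shock, 0.000368 for glucocorticoid-responsive genes, 0.000794 for astrocytes, 0.0111 for choroid plexus and 0.0118 for DNA methylation machinery. They were 0.0316 for oligodendrocytes (28 of 33 above 0), 0.042 for dentate granule neurons (16 of 21), 0.000368 for the nuclear-encoded respiratory chain (10 of 75 above 0, median -0.055) and 0.0299 for neocortex (7 of 21, median -0.206). Fry called 1 list, DNA methylation machinery (adjusted p = 0.00257), and in a test chosen after seeing the data this list had camera adjusted p = 0.187 without Dnmt3a itself. Of its 21 measured members, Dnmt3a alone rose, both over all genes and adjusted over the list alone. Adjusted over the list alone, 7 heat shock genes rose and 1 fell, 2 granule markers rose and 1 fell, and 1 neocortex marker fell. Over all genes tested, Calb1 was the 1 granule marker that rose, and no heat shock or neocortex member was called by edgeR.

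Leaving out Dnmt3a2_1d replicate 1 ended the camera calls at 1 day of the interferon response (adjusted p = 0.0587), choroid plexus (0.917), the respiratory chain (0.917), neocortex (0.136) and dentate granule neurons (0.722), and turned the direction of the oligodendrocyte list (camera adjusted p of oligodendrocytes at 1 day 0.982). Without Control_1d replicate 3, the calls of choroid plexus (0.0625), the respiratory chain (0.54), neocortex (0.206) and oligodendrocytes (0.43) ended. Without Dnmt3a2_1d replicate 4 the glucocorticoid list had adjusted p = 0.187. The granule list lost its call without Control_1d replicate 1 (0.0821) or 4 (0.481), Dnmt3a2_1d replicate 2 (0.165) and Control_5d replicate 2 (0.0522), 3 (0.0519) or 4 (0.0516). The oligodendrocyte list also lost it without Control_1d replicate 1 (0.0821) or Dnmt3a2_1d replicate 3 (0.749). Without the 3 interferon-rich libraries, a choice made after seeing the data, astrocytes and neocortex had adjusted p = 0.0793, choroid plexus 0.573 and granule neurons 0.57. Without the 2 choroid-rich libraries, also chosen then, camera adjusted p was 0.0508 for the methylation list, 0.818 for choroid plexus, 0.688 for granule neurons, 0.13 for neocortex and 0.913 for the respiratory chain. The heat shock list kept its camera call in each of these fits.

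At 5 days, the comparison asks the same at a later time after conditioning. Frem3 (ENSMUSG00000042353, chromosome 8, 80611080 to 80695356), an extracellular matrix protein, rose 3.40-fold from 1.16 ± 0.181 to 3.95 ± 1.38 CPM (SE of log2 0.26, edgeR adjusted p = 0.00177). Fst (ENSMUSG00000021765, chromosome 13, 114452290 to 114458951), follistatin, an activin antagonist, rose 2.69-fold from 1.73 ± 0.432 to 4.65 ± 1.00 CPM (SE of log2 0.20, edgeR adjusted p = 0.00119). Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), a transcriptional repressor in the Notch pathway, rose 1.77-fold from 10.1 ± 0.603 to 17.9 ± 2.45 CPM (SE of log2 0.10, edgeR adjusted p = 0.000265). Htr2a rose 1.79-fold from 11.4 ± 1.68 to 20.4 ± 2.46 CPM (edgeR adjusted p = 0.00299), and Grem1 1.73-fold from 7.36 ± 2.08 to 12.8 ± 1.55 CPM (edgeR adjusted p = 0.0289). C1ql2 (ENSMUSG00000036907, chromosome 1, 120340582 to 120343174), a synaptic organiser secreted by granule cell mossy fibres, fell from 194 ± 19.2 to 128 ± 5.58 CPM (log2 -0.60, SE 0.08, edgeR adjusted p = 0.00119).

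Other falls at 5 days included Hkdc1 (log2 -1.53, SE 0.21, edgeR adjusted p = 0.00119) and Umodl1 (-0.91, SE 0.18, edgeR adjusted p = 0.0289). The hydrolase gene Cmbl fell from 4.63 ± 0.466 to 2.11 ± 0.385 CPM (edgeR adjusted p = 0.00136), the secreted protease gene Klk10 from 4.08 ± 0.699 to 1.75 ± 0.344 CPM (edgeR adjusted p = 0.0299) and Minar2 from 26.4 ± 1.49 to 18.5 ± 0.636 CPM (edgeR adjusted p = 0.000674). Dnah1, an axonemal dynein heavy chain, fell from 8.09 ± 0.458 to 4.81 ± 0.294 CPM, and Rnf39 from 5.42 ± 0.355 to 3.37 ± 0.122 CPM (edgeR adjusted p = 0.0299 and 0.0335). Overlaps leave some changes uncertain. Counts of Ecm2 rose 2.22-fold to 10.1 ± 1.69 CPM (edgeR adjusted p = 0.000262). Those of Cpne7 (ENSMUSG00000034796, chromosome 8, 123117374 to 123135182), a calcium-dependent phospholipid-binding protein that also overlaps Gm20388, rose 2.16-fold from 60.1 ± 7.80 to 130 ± 9.31 CPM (edgeR adjusted p = 0.00113). Acta1 counts fell from 7.70 ± 0.80 to 2.61 ± 0.338 CPM (log2 -1.56, SE 0.16, edgeR adjusted p = 2.5e-05).

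Several fixed lists had members that changed at 5 days. Penk, a member of both the late activity-regulated and the neuropeptide lists, rose 0.61 (SE 0.08, edgeR adjusted p = 0.00113). It was the 1 called gene among 31 late activity-regulated and 27 neuropeptide genes, while adjusted over the list alone 2 rose and 1 fell, and 3 rose and 2 fell. In the postsynaptic list of 45, Ppp1r1b (DARPP-32, a phosphatase inhibitor in dopamine signalling) rose by log2 0.45 (SE 0.09, edgeR adjusted p = 0.0299). Camk2a, the alpha subunit of calcium/calmodulin kinase II, fell from 8575 ± 498 to 7426 ± 204 CPM (log2 -0.21, SE 0.04, edgeR adjusted p = 0.0448). Adjusted over the list alone these counts were also 1 and 1. Of 21 dentate granule markers, Calb1 rose by 0.35 and C1ql2 fell, with 2 rising and 4 falling adjusted over the list alone. Of 20 ventral hippocampus and subiculum markers, Lypd1, which overlaps Gpr39 and is uncertain, fell from 104 to 77.2 CPM (edgeR adjusted p = 0.0104), and 1 fell adjusted over the list alone. Of 57 protocadherins, Pcdhac1, which shares exons with the rest of its cluster and is uncertain, fell by 0.66 (SE 0.14, edgeR adjusted p = 0.0335), also the 1 fall adjusted over the list alone.

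Markers of CA3 and CA2 pyramidal neurons lay higher at 5 days in 18 of 21 (median log2 0.182). Cpne9 rose from 29.5 to 40.6 CPM (edgeR adjusted p = 0.014), and 3 rose adjusted over the list alone. Mitochondrially encoded mRNAs lay lower in 13 of 13 (median -0.167). The lowest score at 5 days was in Dnmt3a2_5d replicate 2 (-0.296), and the other Dnmt3a2_5d libraries scored -0.092 to -0.009. Dnmt3a2_1d replicate 1, which is outside this comparison, scored -0.327. Camera called 6 of 40 lists, and each had adjusted p = 0.992 with an estimated correlation. Up were CA3 and CA2 neurons (adjusted p = 0.000111) and choroid plexus (0.0343, 25 of 25 above 0). Down were mitochondrial mRNAs (0.000844), neocortex (0.0118, 3 of 21 above 0), ribosomal proteins (0.0172, 18 of 79 above 0) and the respiratory chain (0.0342, 19 of 75 above 0). Fry called DNA methylation machinery alone (adjusted p = 0.027), where Dnmt3a was again the 1 called member. In the choroid plexus, ribosomal, respiratory, neocortex and mitochondrial lists no member was called by edgeR over all genes or adjusted over the list alone.

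With GC offsets, chosen after seeing the data, the median of the ribosomal list at 5 days went from -0.059 to -0.005 and that of the respiratory list from -0.045 to -0.008, and camera was not run on that fit. The CA3 and CA2 call at 5 days held without any single library. Without Dnmt3a2_5d replicate 2, the mitochondrial list had camera adjusted p = 0.0545 and the respiratory list 0.817, and the ribosomal list turned direction (camera adjusted p of ribosomal proteins at 5 days 0.865). Without Control_5d replicate 3 the respiratory list had 0.448 and the ribosomal list 0.651. Without Dnmt3a2_5d replicate 4 the neocortex list had 0.0679 and the respiratory list 0.0565. The choroid plexus list had 0.141, 0.0952 and 0.252 without Control_5d replicates 1, 2 and 4, and turned direction without Dnmt3a2_5d replicate 1 (camera adjusted p of choroid plexus at 5 days 0.409).

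**Figure D3:**
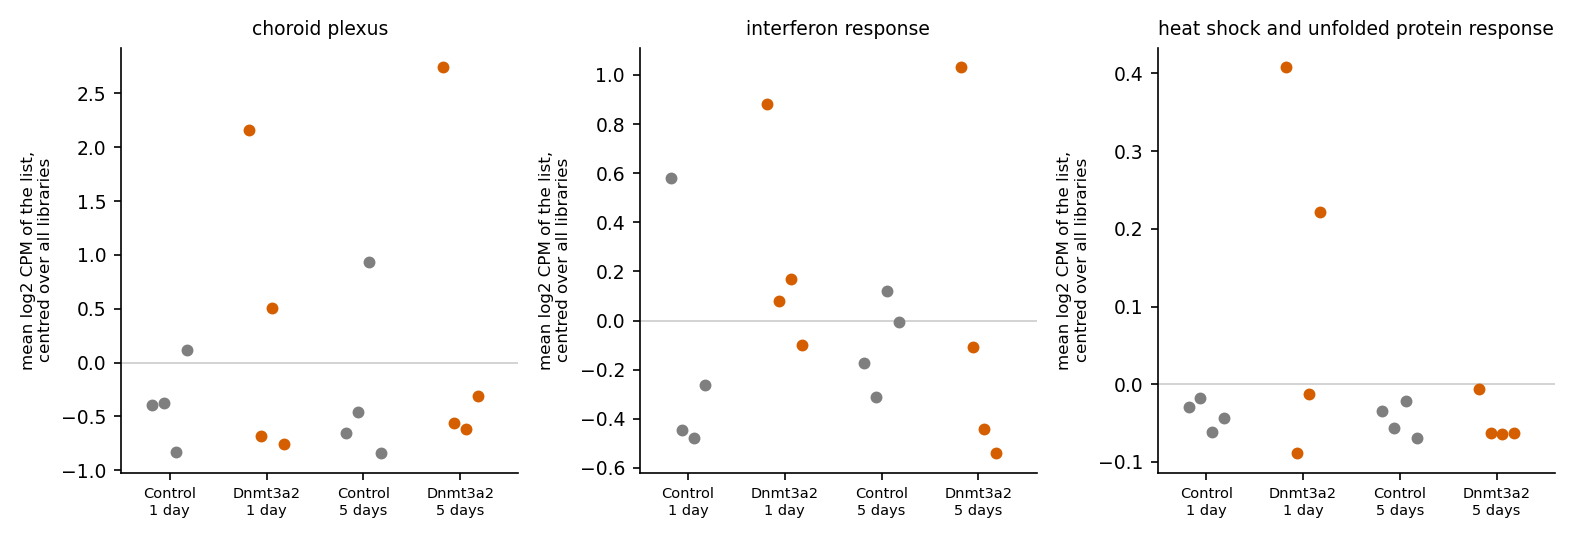
Mean log2 CPM of the choroid plexus, interferon response and heat shock lists, centred over all 16 libraries, with dots for libraries by group. Dnmt3a2_5d replicate 1 and Dnmt3a2_1d replicate 1 stand highest for choroid plexus, at 2.744 and 2.163, and for interferon response, at 1.032 and 0.88.

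In edgeR, 54 genes passed an adjusted p of 0.05 at 5 days, 25 higher and 29 lower, and 1354 passed at an unadjusted p under 0.05. Of the 54, 12 changed by more than 1 on the log2 scale and 7 were predicted or unnamed genes. In all 54 the libraries of the groups did not overlap, against a chance share of 2.86% and 6.29% of all genes observed. Selection by the call favours such separation here too. The count was 22 without Dnmt3a2_5d replicate 4, 26 without Control_5d replicate 4, 29 without Control_5d replicate 1, 30 without Control_5d replicate 3, 33 without Dnmt3a2_5d replicate 3 and 82 without Control_1d replicate 3. It was 90 without the 2 choroid-rich libraries, 105 without the 3 interferon-rich libraries, 98 with the choroid plexus score as a covariate and 85 with GC offsets, choices made after seeing the data. The fit without the 2 choroid-rich libraries ended the calls of Camk2a, Grem1, Pcdhac1 and Ppp1r1b (edgeR adjusted p = 0.0528 to 0.0716), and that without the 3 interferon-rich libraries those of Camk2a and Grem1 (edgeR adjusted p = 0.0566 and 0.0775). DESeq2 called 143. The calls of Frem3, Fst, Cpne7, Hes1, Ecm2, Htr2a, Penk, Acta1, Hkdc1, Cmbl, Minar2 and C1ql2 held under each of 32 alternatives. Each of the other 12 named genes lost its call without Control_5d replicate 4 and without Dnmt3a2_5d replicate 4 (edgeR adjusted p = 0.056 to 0.181). Leaving out Control_5d replicate 1, 2 or 3 or Dnmt3a2_5d replicate 1, 2 or 3 ended 6 to 9 of these calls, and leaving out Control_1d replicate 2 or Dnmt3a2_1d replicate 2 ended that of Camk2a (edgeR adjusted p = 0.0634 and 0.0678).

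Genes called at either day moved in the same direction at both. Of the 59 genes called at either day, 59 had the same sign at both, against 62.7% of all genes. At both days 10 were called: 7 higher, where 0.013 would be shared if the calls were independent, and 3 lower, where 0.010 would be. The 10 were Dnmt3a, Penk, Net1, Ecm2, Htr2a, Grem1, Calb1, Acta1, Hkdc1 and Umodl1. Dnmt3a, the delivered gene, is 1 of the 7 higher. The figures for independent calls treat all genes as equally easy to call, while both days shared 1 fit. Across 16899 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.262 and Spearman rho = 0.307. The jackknife SD of r over the 16 libraries was 0.152, so r lay within 2 SD of 0. Without Dnmt3a, Pearson r was 0.250. Pearson r was 0.146 without Dnmt3a2_1d replicate 1, 0.155 without Dnmt3a2_5d replicate 1, 0.176 without Control_1d replicate 3 and 0.173 without Control_5d replicate 2. Without the 3 interferon-rich libraries it was 0.117.

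**Figure D4:**
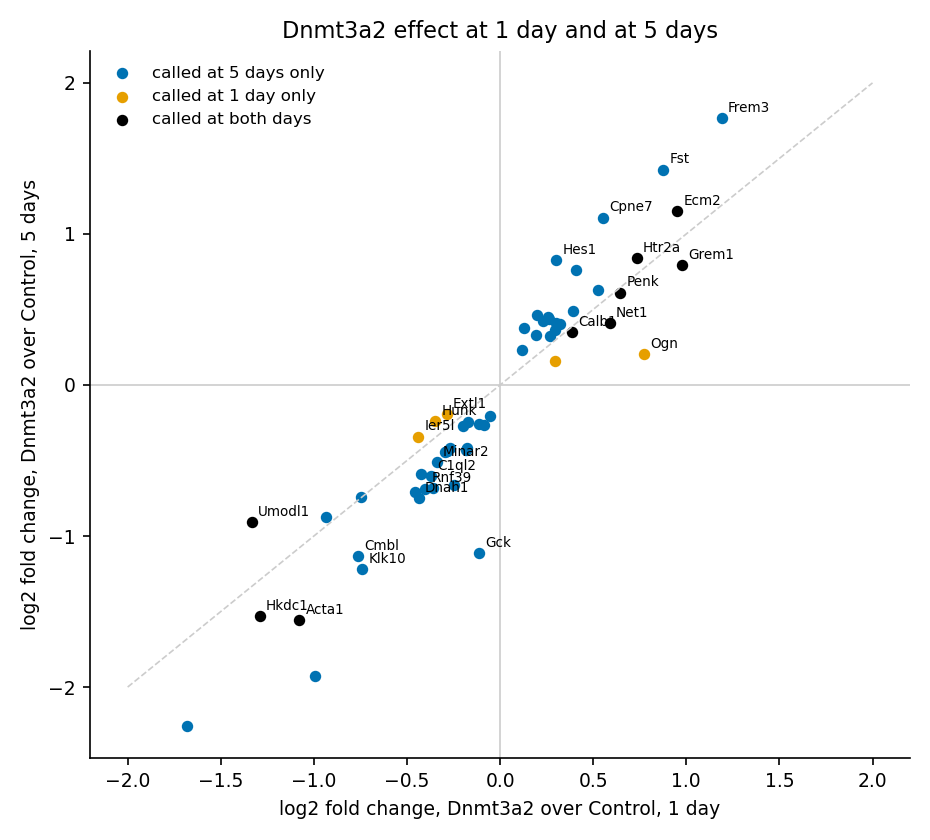
Log2 fold change of Dnmt3a2 against control at 1 day (x axis) and at 5 days (y axis) for genes called at either day, with Dnmt3a left out. Points are genes, blue if called at 5 days alone, orange at 1 day alone and black at both, and the dashed line marks equal effects. All points lie in the quadrants of equal sign.

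Averaging both days asks which changes are shared and uses all 16 libraries. Rises included those of Frem3 (log2 1.48, SE 0.19, edgeR adjusted p = 0.000173), Fst (1.15, SE 0.14, edgeR adjusted p = 0.000117), BC030499 (1.07, SE 0.20, edgeR adjusted p = 0.00821) and Grem1 (0.88, SE 0.11, edgeR adjusted p = 0.000173). Htr2a rose by 0.79 (SE 0.09, edgeR adjusted p = 9.89e-05), Penk by 0.63 (SE 0.06, edgeR adjusted p = 5.11e-06) and Net1 by 0.50 (SE 0.05, edgeR adjusted p = 2.78e-05). Mc4r, the melanocortin 4 receptor, rose by 0.67 (SE 0.12, edgeR adjusted p = 0.00352), from 4.67 ± 1.22 to 7.11 ± 0.623 CPM at 1 day and from 4.66 ± 0.805 to 7.75 ± 1.15 CPM at 5 days. Falls included those of Hkdc1 (-1.41, SE 0.15, edgeR adjusted p = 2.78e-05), Umodl1 (-1.12, SE 0.13, edgeR adjusted p = 5.8e-05) and Cmbl (-0.95, SE 0.11, edgeR adjusted p = 0.000117). Cst6, a cysteine protease inhibitor, changed by -0.64 (SE 0.16, edgeR adjusted p = 0.0442), the keratin gene Krt9 by -0.54 (SE 0.10, edgeR adjusted p = 0.00485) and Minar2 by -0.43 (SE 0.05, edgeR adjusted p = 3.69e-05). Overlapping genes, uncertain for that reason, were Ecm2 (1.05), Acta1 (-1.32), Sla2 (-1.21, overlapping Rab5if at 31.1 CPM) and Zfp941 (-0.76, overlapping Gm45785), with edgeR adjusted p = 4.12e-06, 8.66e-07, 0.00352 and 0.032.

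Some synaptic and channel lists had members that changed in the average. Among 39 glutamate receptor genes, Cacng2 (stargazin, an AMPA receptor auxiliary subunit) rose by 0.17 and Grm4 changed by -0.28 (edgeR adjusted p = 0.0388 and 0.0408), and 3 rose and 1 fell adjusted over the list alone. Gabra2, a GABA-A receptor subunit, rose by 0.19 (edgeR adjusted p = 0.0186), the 1 call among 25 GABA genes also adjusted over the list alone. In the postsynaptic list Ppp1r1b rose by 0.35 and Dlg2 (PSD-93) by 0.13, while Camk2a changed by -0.13 (edgeR adjusted p = 0.00503, 0.041 and 0.0383), with 2 rising and 1 falling adjusted over the list alone. Of 43 presynaptic genes, the calcium sensor Doc2a, which overlaps Ino80e (43.8 CPM) and is uncertain, changed by -0.36, and Stx1a (syntaxin 1A) by -0.20 (edgeR adjusted p = 0.0065 and 0.0328). Adjusted over the list alone 4 rose and 4 fell. Of 47 potassium channel genes, Kcnv1 rose by 0.25 and Kcnab3 changed by -0.36 (edgeR adjusted p = 0.0369 and 0.0239), with 4 rising and 3 falling adjusted over the list alone.

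Some activity-regulated and cell type lists also had changed members in the average, in both directions in some and in 1 direction in others. The immediate early gene Jun rose by 0.18 (edgeR adjusted p = 0.0328), the 1 call among 35 immediate early genes, with 2 rising and 2 falling adjusted over the list alone. Penk and Inhba, an activin subunit (0.38, edgeR adjusted p = 0.0346), rose among 31 late activity-regulated genes, with 5 rising and 1 falling adjusted over the list alone. Penk was the 1 call among 27 neuropeptides (3 rose and 2 fell adjusted over the list alone). Of 21 dentate granule markers Calb1 (0.37) and Jun rose, and C1ql2 (-0.49) and Dsp, desmoplakin (-0.24), fell (edgeR adjusted p = 0.000198, 0.0328, 0.000117 and 0.0315), with 3 rising and 3 falling adjusted over the list alone. Of 14 CA1 markers Spink8 rose by 0.35 and Pou3f1 changed by -0.19 (edgeR adjusted p = 0.0192 and 0.0397), with 2 rising and 2 falling adjusted over the list alone. Stmn1, stathmin (-0.26), fell among 30 neurogenesis genes, Lypd1 (-0.31) among ventral markers, Lpl, lipoprotein lipase (-0.32), among 38 microglial genes and the imprinted gene Grb10 (-0.26) among 38 imprinted genes (edgeR adjusted p = 0.036, 0.00389, 0.00279 and 0.00773). Adjusted over the list alone, 1 neurogenesis gene rose and 2 fell, and 1 gene fell in each of the other lists named in that sentence. Ogn, uncertain because of Cenpp, rose by 0.49 among 23 meningeal genes (edgeR adjusted p = 0.0171), and Pcdhac1, uncertain as above, changed by -0.46 among the protocadherins (edgeR adjusted p = 0.0192), each the 1 call adjusted over the list alone. Ptx3, which overlaps Veph1 and stayed under 1 CPM, rose by 1.18 among 27 reactive astrocyte genes (edgeR adjusted p = 0.0193), where 2 rose adjusted over the list alone.

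Camera called 10 lists in the average, and each had adjusted p = 0.923 with an estimated correlation. Up were interferon response (49 of 53 above 0, median 0.290, adjusted p = 0.00232), choroid plexus (25 of 25, 1.351, 0.00264), glucocorticoid-responsive genes (23 of 29, 0.104, 0.00264), CA3 and CA2 neurons (17 of 21, 0.094, 0.000919), heat shock (29 of 38, 0.092, 0.0091) and astrocytes (22 of 28, 0.063, 0.0223). Down were the respiratory chain (10 of 75 above 0, median -0.058, adjusted p = 0.000803), neocortex (4 of 21, -0.164, 0.00264), mitochondrial mRNAs (0 of 13, -0.131, 0.00414) and ribosomal proteins (18 of 79, -0.042, 0.0145). Fry called DNA methylation machinery alone (adjusted p = 0.000333), where Dnmt3a was the 1 called member. Without Dnmt3a, a test chosen after seeing the data, this list had camera adjusted p = 0.49. The form of fry for changes in either direction called 15 of 40 lists in the average, 5 at 1 day and 6 at 5 days. Between days it called 1 in Dnmt3a2 mice and 0 in controls, and for the interaction 0. Among members of the lists called by camera, Cpne9 (0.33) rose in the CA3 and CA2 list and the glutamate transporter Slc1a3 (0.19) among astrocyte markers. Scnn1a (-0.28) fell in the neocortex list (edgeR adjusted p = 0.00485, 0.0426 and 0.015 for the 3 genes). Adjusted over the list alone, 7 rose in the CA3 and CA2 list, 3 among astrocyte markers and 3 among glucocorticoid-responsive genes, while 1 rose and 4 fell in the neocortex list. The interferon and choroid plexus lists moved with Dnmt3a2_1d replicate 1 and Dnmt3a2_5d replicate 1, the libraries richest in these transcripts.

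The CA3 and CA2 and the neocortex calls in the average held without any single library. Without Dnmt3a2_1d replicate 1, camera adjusted p was 0.127 for interferon response, for heat shock and for mitochondrial mRNAs, 0.129 for choroid plexus and the respiratory chain, 0.124 for astrocytes and 0.413 for ribosomal proteins. Without Dnmt3a2_5d replicate 1 it was 0.349 for interferon response, 0.272 for choroid plexus and 0.0816 for astrocytes. Without Dnmt3a2_1d replicate 4 it was 0.0817 for glucocorticoid-responsive genes, 0.0527 for heat shock and 0.091 for astrocytes. The respiratory chain had 0.0644 without Control_1d replicate 3, and astrocytes 0.0533, 0.0708 and 0.0968 without Control_1d replicate 1, Control_5d replicate 1 and Control_5d replicate 2. Ribosomal proteins had 0.486, 0.17, 0.256, 0.0845 and 0.56 without Control_1d replicate 3, Control_1d replicate 4, Control_5d replicate 3, Dnmt3a2_1d replicate 2 and Dnmt3a2_5d replicate 2. In fits chosen after seeing the data, without the 2 choroid-rich libraries camera adjusted p was 0.149 for astrocytes and heat shock, 0.12 for mitochondrial mRNAs and 0.0762 for ribosomal proteins. Without the 3 interferon-rich libraries it was 0.248 for astrocytes, 0.181 for heat shock, 0.109 for interferon response and 0.0526 for glucocorticoid-responsive genes. The choroid plexus list lost its call and turned direction in both of these fits. The interferon response list did so without the 2 choroid-rich libraries. GC offsets, also chosen then, moved the median of the ribosomal list in the average from -0.042 to -0.005 and that of the respiratory list from -0.058 to -0.029.

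In edgeR, 241 genes passed an adjusted p of 0.05 in the average, 119 higher and 122 lower, and 2049 passed at an unadjusted p under 0.05. All 241 had the same sign at both days, against 62.7% of all genes, but selection on the average of the days favours such genes. At neither day alone were 182 of them called. Most changes were small: 176 of the 241 lay under 0.5 on the log2 scale, 21 over 1, and the median was 0.31. Libraries did not overlap within either day for 90 of the 241, against 0.73% of all genes, which selection by the call also favours. The count was 121 without Control_5d replicate 4, 128 without Dnmt3a2_5d replicate 4, 141 without Control_5d replicate 1, 144 without Control_1d replicate 2, 146 without Control_5d replicate 2 and 154 without Dnmt3a2_5d replicate 3. DESeq2 called 512. Each of the 16 libraries ended 4 to 18 calls of named genes when left out (edgeR adjusted p = 0.0502 to 0.105). The genes concerned included Cacng2, Camk2a, Cst6, Dlg2, Dsp, Grm4, Inhba, Jun, Kcnab3, Kcnv1, Pcdhac1, Pou3f1, Ptx3, Slc1a3, Spink8, Stmn1, Stx1a and Zfp941. In fits chosen after seeing the data, the 2 choroid-rich libraries left out ended the calls of Cacng2, Cst6, Dlg2, Grm4, Inhba, Pcdhac1, Slc1a3, Stmn1 and Stx1a (edgeR adjusted p = 0.051 to 0.104). The 3 interferon-rich libraries left out ended those of Cst6, Grm4, Inhba, Pou3f1, Ptx3 and Slc1a3 (edgeR adjusted p = 0.0534 to 0.149). GC offsets ended calls that included those of Gabra2, Jun, Cacng2, Dlg2, Kcnab3, Stmn1 and Slc1a3. The calls of Frem3, Fst, Grem1, Htr2a, Penk, Net1, Mc4r, Calb1, Ppp1r1b, Hkdc1, Umodl1, Cmbl, Minar2, C1ql2 and Lpl held under each alternative.

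Between 5 days and 1 day in control mice, the comparison asks what differs between the 2 times after conditioning. The labels name no unconditioned group, so ageing of the memory cannot be told apart from time since the shock, time since injection or collection. No gene passed in edgeR, with 598 at an unadjusted p under 0.05 and a lowest adjusted p of 0.999, and DESeq2 and limma-voom also called 0. The genes with the smallest p are given as values: Chrdl1, a BMP antagonist, was at 4.52 ± 0.392 CPM at 1 day and 6.81 ± 0.676 CPM at 5 days (log2 0.59, SE 0.12). Cyp2d22 was at 32.9 ± 3.19 and 25.4 ± 1.98 CPM (-0.37, SE 0.08) and Ogn at 5.53 ± 1.44 and 8.35 ± 0.457 CPM (0.59, SE 0.15). Kbtbd6 was at 0.804 ± 0.0577 and 1.39 ± 0.235 CPM, and Prr36, which overlaps Evi5l (87.1 CPM), at 54.7 ± 4.05 and 64.4 ± 2.59 CPM. Dnmt3a was at 34.8 and 35.1 CPM (log2 0.02, SE 0.15, edgeR adjusted p = 0.999).

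Between the days in Dnmt3a2 mice, no gene passed in edgeR either, with 1822 at an unadjusted p under 0.05 and a lowest adjusted p of 0.187. DESeq2 called 44, limma-voom 0, edgeR without a low-count filter 6, and edgeR without Dnmt3a2_5d replicate 1 called 1. Slc19a3, a thiamine transporter, was at 3.26 ± 0.83 CPM at 1 day and 1.52 ± 0.0751 CPM at 5 days (log2 -1.10, SE 0.20). Zcchc24 was at 81.4 ± 7.79 and 61.9 ± 4.40 CPM (-0.40, SE 0.07) and Lrp1b, a lipoprotein receptor relative, at 22.3 ± 1.18 and 27.9 ± 2.06 CPM (0.33, SE 0.07). The clock gene Per3, which overlaps Camta1 (368 CPM), was at 28.2 ± 1.81 and 22.7 ± 0.726 CPM, and Mgat2, which overlaps Gm49383, at 27.7 ± 1.19 and 33.7 ± 1.29 CPM. Dnmt3a differed by 0.27 (SE 0.14, edgeR adjusted p = 0.524).

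The interaction asks whether the Dnmt3a2 effect differs between days. No gene passed in edgeR, with 360 at an unadjusted p under 0.05 and a lowest adjusted p of 1. DESeq2 called 1 and limma-voom 0. Hes1 had the difference 0.52 (SE 0.14), with 10.8 ± 1.07 and 13.3 ± 1.18 CPM at 1 day and 10.1 ± 0.603 and 17.9 ± 2.45 CPM at 5 days in Control and Dnmt3a2. Mgat2 had 0.27 (SE 0.08), the protease gene Furin 0.25 (SE 0.08) and Cand2, which overlaps Rpl32 (104 CPM), 0.48 (SE 0.15). A call at 5 days that was absent at 1 day, as for Hes1, was therefore not shown to differ between days (edgeR adjusted p = 1).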

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

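The tests on the Y-linked genes, the choroid plexus markers and the granule cell markers were chosen only after the result was seen.

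One control library, Control_5d replicate 3, held low counts from the Y chromosome: Uty was at 2.46 CPM against 8.14 to 9.13 CPM in the other Control_5d libraries, Ddx3y at 8.66 against a mean of 27.8, Kdm5d at 3.84 against 13.5 and Eif2s3y at 3.73 against 9.63. RNA from female mice would bring Xist, the transcript of the inactive X, and the library had 0 Xist counts where the highest of the other 15 had 2. Library size or normalization is argued against by the counts before any scaling, where its median gene lay at 0.959 of the other controls and the 4 Y-linked genes at 0.272 to 0.372. Loss of the Y chromosome in part of the cells remains open as a hypothesis: the 4 genes lay at 0.285 to 0.388 of the other controls, ratios that spread by 1.36, and the X-linked counterparts at 0.775 to 1.03, though Kdm6a, at 16.3 CPM, lay below the lowest of the other 15 libraries (16.7 CPM). The design gives no group that separates this library, so no biological explanation by group was tested.

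Choroid plexus transcripts were high in Dnmt3a2_5d replicate 1, whose score of 2.744 lay far from the -0.613 to -0.309 of its group, and in Dnmt3a2_1d replicate 1 (2.163). Choroid plexus tissue in the dissected sample is a candidate explanation that was not decided: 25 of 25 markers, all of which passed the expression filter here, were higher in both libraries than in every other Dnmt3a2 library, but the libraries were picked on these same markers. Ttr was at 773.3 and 1253 CPM and Enpp2, which other brain cells also express, at 303.3 and 433.1 CPM in these libraries, against 5.511 to 157.2 and 84.33 to 160.1 CPM elsewhere, with both highest values elsewhere in a control library, Control_5d replicate 3. Without the 2 libraries, 241 of the 241 genes called in the average kept their direction and at least 0.5 of their log2 change. Of these, 166 were still called. The genes were picked with the 2 libraries included, and most libraries stayed in the fit. The calls therefore did not rest on these 2 libraries alone, but the test cannot exclude a part for the tissue. A response of the choroid plexus shared by the Dnmt3a2 libraries is argued against. The other Dnmt3a2 libraries scored -0.753 to 0.506, below Control_5d replicate 3 (0.934). Their Dnmt3a lay at 982.3 to 1249 CPM, against 623.2 and 1015 CPM in the 2 libraries. Dissection stays open, as does a response limited to these 2 libraries.

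C1ql2 and Dsp, markers of dentate granule neurons, fell with Dnmt3a2 (log2 -0.49 and -0.24 in the average). A smaller share of granule neurons would lower the other markers by about as much as C1ql2. The 19 others had a median of 0.08 with an interquartile range of 0.14, ran from -0.23 to 0.37, and 13 lay above 0, which argues against that explanation. C1ql2 and Dsp were set apart because they were called as falling, so their distance from the others is partly selected. Among the others, Lct (-0.23) lay close to Dsp, and Calb1 (0.37) and Jun (0.18) were called as rising. An effect of Dnmt3a2 on C1ql2 and Dsp within granule neurons remains open as a hypothesis, as do other technical causes not tested for them.

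Chance sets about 1 in 20 groups of 4 libraries apart by the test used for single libraries. It did so for 15 of 284 gene and group pairs (14.2 by chance), 5 of 68 cell type scores (3.4 by chance) and 2 of 4 group totals (0.2 by chance). Total counts were 28.7 M in Control_1d replicate 4 against 29.9 M in the others, and 29.7 M in Dnmt3a2_1d replicate 4 against 28.8 to 28.9 M. Single libraries that stood high in their group, with the range of the other libraries, were Control_1d replicate 1 for Cacng2 (108 CPM against 101 to 102), Control_1d replicate 2 for Inhba (6.0 against 5.29 to 5.4), Control_5d replicate 3 for Cpne9 (35.0 against 27.2 to 28.4) and Control_5d replicate 4 for Lypd1 (107 against 103 to 104). In the Dnmt3a2 groups, Dnmt3a2_1d replicate 2 stood high for Cst6 (1.49 against 1.2 to 1.24), Dnmt3a2_1d replicate 1 for Klk10 (4.19 against 1.94 to 2.19), and Dnmt3a2_5d replicate 2 for Dlg2 (381 against 358 to 360) and Hunk (56.1 against 53.1 to 53.5). Libraries that stood low were Control_5d replicate 3 for Grb10 (16.7 against 17.7 to 17.8) and Grem1 (4.26 against 8.18 to 8.63), and Dnmt3a2_5d replicate 1 for Htr2a (16.7 against 21.4 to 21.8). Dnmt3a2_1d replicate 4 stood low for Hunk (41.4 against 50.3 to 52.1) and Ptx3 (0.381 against 0.758 to 0.824), and Dnmt3a2_5d replicate 4 for Uty (7.80 against 8.68 to 8.82). Among marker scores, astrocytes were at -0.001 in Dnmt3a2_5d replicate 1 (others -0.032 to -0.028) and oligodendrocyte precursors at -0.040 in Control_5d replicate 4 (others 0.015 to 0.023). Blood genes were at -0.009 in Dnmt3a2_1d replicate 4 (others -0.279 to -0.246) and 0.515 in Dnmt3a2_5d replicate 3 (others -0.001 to 0.065).

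The Dnmt3a2 effect on 5 gene lists differed between the days by camera on the interaction. The effect was lower at 5 days than at 1 day for heat shock genes (median difference -0.154, adjusted p = 4.8e-05), interferon response genes (-0.055, 0.0113), dentate granule markers (-0.093, 0.0113) and astrocyte markers (-0.059, 0.0375), and higher at 5 days for protocadherins (0.094, 0.0375). Each had adjusted p = 0.976 with an estimated correlation, and no member was called by edgeR over all genes or adjusted over the list alone. The heat shock difference held without any single library. Without the 2 choroid-rich and without the 3 interferon-rich libraries, fits added after the data were seen, the granule difference (0.413 and 0.682) and the astrocyte difference (0.0571 and 0.24) ended. The interferon difference ended without Control_1d replicate 2 (0.142) or 3 (0.182), Control_5d replicate 4 (0.0664), Dnmt3a2_1d replicate 1 (0.495) and Dnmt3a2_5d replicate 3 (0.216) or 4 (0.313). The granule difference ended without Control_1d replicate 4 (0.202), Control_5d replicate 4 (0.0825), Dnmt3a2_1d replicate 1 (0.114) or 2 (0.051) and Dnmt3a2_5d replicate 1 (0.0857). The astrocyte difference ended without Control_1d replicate 1 (0.204) or 2 (0.129), Control_5d replicate 3 (0.321) or 4 (0.0864), Dnmt3a2_1d replicate 1 (0.144) or 4 (0.246) and Dnmt3a2_5d replicate 2 (0.0543), 3 (0.0592) or 4 (0.0597). The protocadherin difference ended without Control_1d replicate 1 (0.239), 2 (0.142) or 3 (0.0715), Control_5d replicate 3 (0.184) or 4 (0.0707), Dnmt3a2_1d replicate 4 (0.66) and Dnmt3a2_5d replicate 2 (0.227), 3 (0.0592) or 4 (0.0597).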

How the results depend on the processing

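The fits without the 2 choroid-rich or the 3 interferon-rich libraries, with the choroid plexus score as a covariate, and with GC and length offsets were chosen only after the data were seen. No called named gene turned direction in any fit. The Dnmt3a rise lay between 4.70 and 4.95 at 1 day and between 5.00 and 5.12 at 5 days on the log2 scale, and the correlation of the effects between 0.117 and 0.370. The genes called at 1 day, 5 days and in the average (15, 54 and 241) numbered 59, 143 and 512 by DESeq2 and 23, 104 and 442 at an adjusted p of 0.10, a looser threshold. A fold of 1.5 left 28 and 52 at 5 days and in the average, a stricter one. The cause of the following counts was not tested. With 1 surrogate variable there were 25 and 90 at 1 and 5 days, with only the groups compared 7 and 94, with the choroid plexus covariate 24 and 98, and without a low-count filter 34 at 1 day. At 5 days there were 90 without the choroid-rich libraries, 105 without the interferon-rich libraries and 85 with GC offsets. With the replicate number as a block the counts were 17, 65 and 295, of which 15, 52 and 227 were shared with the unblocked calls. Leaving out single libraries gave 6 (Control_1d replicate 2) to 22 (Dnmt3a2_1d replicate 4) at 1 day, 22 (Dnmt3a2_5d replicate 4) to 82 (Control_1d replicate 3) at 5 days and 121 (Control_5d replicate 4) to 272 (Dnmt3a2_5d replicate 1) in the average, where fewer samples were compared. Between days in controls edgeR called 0 genes throughout (598 at an unadjusted p under 0.05, 0 by DESeq2). In Dnmt3a2 mice, where edgeR called 0 (1822 at an unadjusted p under 0.05), there were 44 by DESeq2, 6 without a filter, 4 with the choroid covariate, 1 with a surrogate variable and 0 to 1 without single libraries (1 without Dnmt3a2_5d replicate 1). The interaction gave 1 by DESeq2 and 0 by edgeR (360 at an unadjusted p under 0.05) without any single library. Dnmt3a log2 fold change, timeC (between days in controls, 0.02), was -0.01 with GC offsets and ran from -0.02 (without Control_5d replicate 1) to 0.05 without single libraries.

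Lists called by camera at 1 day, 5 days, in the average, between days in controls and in Dnmt3a2 mice, and for the interaction (10, 6, 10, 8, 16 and 5) numbered 0 in all with an estimated correlation, and 1, 1, 1, 0, 0 and 0 by fry, a different question. Without single libraries they ran from 8 to 16 (highest without Dnmt3a2_1d replicate 4), 4 to 13 (highest without Dnmt3a2_5d replicate 1, 10 without replicate 3), 4 (without Dnmt3a2_1d replicate 1) to 14, 3 (without Control_1d replicate 4; 5 without Control_5d replicate 4) to 14 (without Control_1d replicate 3), 14 to 19, and 1 (without Control_5d replicate 4) to 14 (without Control_1d replicate 4). Without the choroid-rich libraries there were 6, 13 and 9 at 1 day, at 5 days and for the interaction, without the interferon-rich 6 and 13 at 1 and 5 days, with a surrogate variable 3, 6 and 10 at 5 days, in the average and for the interaction, and with the choroid covariate 9 for the interaction. The following turned direction, and the cause was not tested: camera adjusted p of oligodendrocytes at 1 day (0.0316; 2.61e-09 to 0.982 without single libraries, turned without Dnmt3a2_1d replicate 1; 0.988 without the choroid-rich and 0.834 without the interferon-rich libraries). The camera adjusted p of ribosomal proteins at 5 days (0.0172) ran from 0.000221 to 0.865, turned without Dnmt3a2_5d replicate 2. The camera adjusted p of choroid plexus at 5 days (0.0343) ran from 0.000209 to 0.409, turned without Dnmt3a2_5d replicate 1, and was 0.325 and 0.318 without the choroid-rich and the interferon-rich libraries. The camera adjusted p of choroid plexus averaged over both days (0.00264; 7.08e-05 to 0.272) was 0.731 and 0.776 in those fits. The camera adjusted p of interferon response averaged over both days (0.00232; 3.16e-07 to 0.349) was 0.652 without the choroid-rich libraries. The camera adjusted p of MHC and complement between days in Dnmt3a2 mice (0.0247) ran from 1.07e-06 to 0.93, turned without Dnmt3a2_1d replicate 1. Simulated changes of 1.2-fold were recovered for 18.0% of genes at 1 day, so small changes are the ones this design misses most.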

Other observations

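None of the tests here was chosen only after its result was seen, though the fits without choroid-rich or interferon-rich libraries and with offsets for GC content and transcript length were added after the data were seen.

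From 1 day to 5 days, several gene lists lay on the same side of 0 in both virus groups. Of the 7 lists named for both groups here, camera on the interaction called a difference between the groups for protocadherins (adjusted p = 0.0375, and 0.976 with an estimated correlation). That call ended (0.0592 to 0.66) without any 1 of Control_1d replicates 1 to 3, Control_5d replicates 3 and 4, Dnmt3a2_1d replicate 4 and Dnmt3a2_5d replicates 2 to 4. The others had camera adjusted p = 0.153 to 0.992, which does not show that their shifts were equal. Ribosomal protein genes lay lower at 5 days in all but 1 of 79 in controls (median log2 -0.102) and all but 2 of 79 with Dnmt3a2 (-0.134). Endothelial and mural markers lay lower (median -0.198 and -0.226, with 1 and 3 of 31 above 0), as did glucocorticoid-responsive genes (-0.138 and -0.191, with 2 and 1 of 29 above 0) and oligodendrocyte markers (-0.077 and -0.181, with 6 and 3 of 33 above 0). Protocadherins, adhesion proteins of neurons, lay higher (0.068 and 0.205, with 43 and 46 of 57 above 0), as did GABA receptor and synthesis genes (0.057 and 0.079, with 21 and 23 of 25 above 0) and blood genes (0.540 and 0.441, with 7 of 7 above 0 in each). In controls dentate granule markers were also above 0 in 18 of 21 (0.082). Camera called 8 of 40 lists in controls, with adjusted p = 1.11e-09 for ribosomal proteins, 1.9e-08 for endothelial and mural cells, 0.000272 for glucocorticoid-responsive genes, 0.00414 for protocadherins and blood, 0.00497 for dentate granule neurons, 0.00633 for oligodendrocytes and 0.0227 for GABA genes. Each had adjusted p = 0.97 with an estimated correlation, fry called 0, and edgeR called no member over all genes or adjusted over the list alone. Without Control_1d replicate 4 the calls in controls of glucocorticoid-responsive genes (0.142), protocadherins (0.416), granule markers (0.416), oligodendrocytes (0.416) and GABA genes (0.783) ended. Others ended without Control_5d replicate 1 (oligodendrocytes 0.413, GABA genes 0.137), Control_5d replicate 2 (protocadherins 0.0765, GABA genes 0.0938), Control_5d replicate 3 (blood 0.285) and Control_5d replicate 4 (granule markers 0.102, oligodendrocytes 0.135, GABA genes 0.0784). Blood also ended without the 3 interferon-rich libraries (0.071).

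In Dnmt3a2 mice camera called 16 lists between the days, 6 up and 10 down. None held: camera adjusted p = 0.667 to 0.781 with an estimated correlation, and fry called 0 for movement in 1 direction. Beside the lists shared with controls, glutamate receptors (30 of 39 above 0, median 0.060, adjusted p = 0.0138), calcium and sodium channels (20 of 27, 0.066, 0.0174) and CA3 and CA2 markers (15 of 21, 0.093, 0.0131) lay higher at 5 days. Heat shock genes (7 of 38 above 0, median -0.151, adjusted p = 4.21e-05), interferon response (18 of 53, -0.120, 0.0129), MHC and complement (8 of 32, -0.313, 0.0247), circadian clock genes (5 of 20, -0.068, 0.0177), astrocytes (3 of 28, -0.101, 0.000188) and reactive astrocytes (8 of 27, -0.160, 0.0311) lay lower. The shared lists had 9.06e-10 for ribosomal proteins, 2.04e-06 for glucocorticoid-responsive genes, 2.71e-05 for endothelial and mural cells, 0.000205 for oligodendrocytes, 7.56e-07 for protocadherins, 0.000416 for GABA genes and 0.0177 for blood. With GC offsets the clock median went from -0.068 to -0.105. EdgeR called no member over all genes, while adjusted over the list alone 6 protocadherins, 3 CA3 and CA2 markers and 1 channel gene rose and 2 clock genes fell. Without Dnmt3a2_1d replicate 1 the calls of glutamate receptors (0.0824), interferon response (0.722), reactive astrocytes (0.651), oligodendrocytes (0.165) and blood (0.169) ended. The MHC and complement list also lost its call without that library, and turned direction. Without Dnmt3a2_1d replicate 2 those of blood (0.147), clock genes (0.0734) and CA3 and CA2 markers (0.058) ended, without Dnmt3a2_1d replicate 3 that of oligodendrocytes (0.0811), and without Dnmt3a2_1d replicate 4 those of clock genes (0.178) and CA3 and CA2 markers (0.0901). Without Dnmt3a2_5d replicate 1 the clock list had 0.0836, and without Dnmt3a2_5d replicate 2 glutamate receptors had 0.102, channels 0.217, MHC and complement 0.0518 and reactive astrocytes 0.117. Without Dnmt3a2_5d replicate 3, interferon response had 0.273, MHC and complement 0.21, reactive astrocytes 0.246 and blood 0.21. Without Dnmt3a2_5d replicate 4, interferon response had 0.471, MHC and complement 0.587, reactive astrocytes 0.217 and CA3 and CA2 markers 0.0637. Without the 2 choroid-rich and without the 3 interferon-rich libraries, the calls of heat shock genes (0.0594 and 0.0853), oligodendrocytes (0.103 and 0.127) and blood (0.137 and 0.165) ended. Libraries outside the comparison, which enter through the shared spread, moved reactive astrocytes to 0.0577 (Control_5d replicate 4) and blood to 0.0514, 0.0503 and 0.0505 (Control_1d replicates 3 and 4, Control_5d replicate 2).

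Germline genes, a class silenced by DNA methylation in somatic tissue, were mostly below the expression filter: 4 of 24 were measured, and none was called by edgeR or adjusted over the list alone in the average (median -0.087, camera adjusted p = 0.675). Of 50 extracellular matrix and perineuronal net genes, 28 lay above 0 and none was called on either scale (camera adjusted p = 0.0703, and 0.923 with an estimated correlation). Ependymal markers (median 0.204, adjusted p = 0.43), interneuron markers (-0.049, 0.558) and thalamic and habenular markers (0.011, 0.945) were not called by camera in the average either.

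Splits of the same libraries into other groups tested whether chance explains the counts of called genes. At 1 day the real split gave 15 genes and the highest of the others 2, so that 1 of 35 splits, the real one, gave as many. This is the smallest share that 35 splits allow, so chance is not excluded. The other splits mix Dnmt3a2 and control libraries within a group, which adds spread and can lower their counts. At 5 days the real split gave 54 and the highest other 2, again 1 of 35 splits. In the average, 1 of 100 splits drawn from 2450 gave as many as 241. The highest other gave 122 and moved 6 libraries between groups, and the next gave 14. At 1 day the split with 122 set replicates 1 and 2 of both virus groups against the other replicates, a grouping balanced for virus. At 5 days it exchanged 1 library of each virus group, so most of the real contrast stayed. Whether its calls came from that contrast or from other structure shared between libraries was not tested, and such structure may also add to the 241. Between days the real split gave 0 genes in each virus group and the highest other 0, and for the interaction 0 against 1. With 0 genes called, every split gives as many (35 of 35, 35 of 35 and 100 of 100), so the splits say nothing about chance there. EdgeR gave 598, 1822 and 360 genes at an unadjusted p under 0.05 in these 3 comparisons, and DESeq2 called 0, 44 and 1.

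GC content or transcript length bias was tested as a source of the 241 calls in the average. With offsets for both, 206 of the 241 kept their call and direction, which argues against such bias as the whole cause, and 280 genes were called, 118 higher and 162 lower.

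A hypothesis that Dnmt3a2 lowers long genes relative to short ones found nothing in its favour. The median change of 2372 genes over 100 kb lay 0.013 above that of 14515 shorter genes at 1 day and 0.018 above it at 5 days (exact two-sided permutation p = 0.743 at each day, 70 regroupings).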
